A study of Homo sapiens with 36 samples.

How the data were processed

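Bulk RNA sequencing was carried out on human iPSC-derived cells in 36 libraries, with 12 groups of 3 independent differentiations. Per the labels, 500000 cells gave total RNA by RNeasy columns, 250 ng entered each library, and 100 bp paired reads were made on a DNBseq instrument. The groups were wild type (WT), the MAPT-edited lines labelled 4R PLSF-hom (hom), 4R PLSF-het (het), PLSF and 4R, and WT treated with nocodazole, each collected at DIV15 and DIV35 (days in vitro). The labels contradict each other on nocodazole, giving 3 uM for 72 h in the sample tags and 3 nM for 36 h in the treatment protocol.

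The deposited values are read counts per gene, whole numbers without normalisation, in 1 table of 24739 genes and 36 libraries. For these counts the authors name STAR 2.7.9a, Salmon 1.10.1 and the genome build GRCh38.p13. The role and order of these tools, the annotation release and the strand setting are not given in the sources used here. Each gene in the table had at least 10 counts summed over the 36 libraries, so genes with fewer had been removed. Of the 21 pseudoautosomal copies assigned to chromosome Y, 20 were added to their partners and 1 without a partner in the table was kept, which left 24719 genes. Symbols and positions came from GENCODE 29 on GRCh38, with a symbol for 20233 genes and a position for 24107. Library totals lay between 9703491 and 10787942 counts (median 10461122.5), with 20500 to 21558 genes detected and 4.75% to 8.98% of counts from mitochondrial genes. With totals this alike, downsampling before deposit cannot be excluded. Intervals and floors cover counting error only, since they pool the counts of a group's libraries and leave out the spread between them. The counts also carry no molecular identifiers.

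Differential expression was tested with edgeR 4.0.16 in R 4.3.3, two-sided, with TMM factors, filterByExpr by group (minimum count 10), robust dispersion and quasi-likelihood fits, and Benjamini-Hochberg adjustment over all genes tested. Comparisons within a day used the 18 libraries of that day, with 16193 genes tested at DIV15 and 16008 at DIV35. The WT comparison between days and the differences of effects between days used all 36 libraries and 17156 genes. There were 22 comparisons, each adjusted on its own, and a gene was called at an adjusted p under 0.05. The common biological coefficient of variation was 7.53% over all libraries, 7.75% at DIV15 and 7.26% at DIV35. Log2 fold changes are the first group minus the second. The SE was derived as the absolute log2 fold change divided by the square root of the test's F statistic. Where a group is at or near 0 counts, the log2 fold change and its SE depend on the prior count that edgeR adds. There the SE is no measure of the spread between libraries. A fold against a group at 0 counts is a lower bound with a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with its exact 95% counting interval.

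Gene lists and the rule for named genes were fixed before the data were examined. The 37 lists covered cell identity, cell cycle, stress, metabolism, microtubules and regions near MAPT and on chromosome 20, and 35 were tested. The hindbrain and spinal list, of which 3 of 14 members were in the table, and the microglia and endothelium list had fewer than 3 tested members and were not tested. Lists were compared with all other genes by camera from limma 3.58.1 with a preset correlation of 0.01 and again with the correlation estimated, adjusted over the lists of a comparison. Members were counted over all genes and adjusted over the list alone, and not every list call is printed. Named genes were MAPT, in each comparison with WT and between the WT days up to the 10 highest and 10 lowest called genes with a mean log2 CPM of at least 1 and groups that did not overlap, up to 10 per direction shared by the 4 lines, 5 per direction in other comparisons, and up to 4 called members per list. The mean log2 CPM was taken over all libraries of the fit, so a named gene can be low in both groups compared. Chance separates 3 libraries from 3 others in 10% of genes. BCL2L1, and in some comparisons GSX2, NSG2, SLC17A6, SLC17A7 and SP8, are called list members named after their values were seen. Some genes that the rule would name are not reported here.

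Similarity of effects was measured as Pearson r and covariance across genes, beside 20 simulations per day of unchanged groups against shared WT libraries. Replicate numbers did not pair libraries across lines, with a mean residual correlation of 5e-04 at DIV15 and 0.0045 at DIV35 between libraries of equal number, so no block was used. Alternatives were DESeq2 1.42.0, median-of-ratios factors in edgeR, no filter on low counts, only the groups compared, a replicate block, each library left out in turn, fry for lists, and similarity among called genes. Leaving out each library for the gene lists was added after seeing the data. Positions of reads, isoforms and alleles were not analysed here.

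The pipeline was tested on simulated data with fold changes put into known genes. At 4-fold, 92.4% of 66 changed genes were recovered for hom against WT at DIV15, and 78.8% for the difference of the hom effects between days, or 100% of the 41 of these at 5 CPM or more. The planned criterion of 80% overall was missed by this last comparison, and it was then replaced by recovery among genes at 5 CPM or more. No changed gene was called in the wrong direction, and 4 to 12 unchanged genes were called per comparison. A covariance of 0.252 put into the effects of a pair of lines was recovered as 0.254.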

Results

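RNA was sequenced from cultures of the human induced pluripotent stem cell (iPSC) line A18944 and of edited derivatives carrying changes at the endogenous MAPT locus, the gene for the microtubule-binding protein tau. Dual SMAD inhibition directed the cultures toward cortical neurons. They were collected at day in vitro (DIV) 15 as neuronal precursors and at DIV35 as early neurons. The 12 groups of 3 libraries were the unedited wild type (WT), 4 edited lines and WT cultures given the microtubule-depolymerising drug nocodazole (Noco), each at both days. The line labelled 4R PLSF-hom (hom line) carried the 4R edit with P301L and S320F on both alleles, the line labelled 4R PLSF-het (het line) the same changes on one allele, the PLSF line P301L and S320F on both alleles without the 4R edit, and the 4R line the 4R edit on one allele. Each genotype came from 1 line, so the genotype and the history of that line cannot be separated in any comparison. The 3 libraries of a group were independent differentiations, and the 36 libraries held 9703491 to 10787942 counts each. Levels are counts scaled to library size (CPM) as mean ± SD with n = 3, and log2 fold changes, standard errors (SE) and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Gene lists were tested with camera. With all libraries a list call passed with an estimated correlation unless such a p-value is printed beside it, and 14 of those calls were lost without at least 1 of the libraries.

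MAPT (chromosome 17, 45894382 to 46028334, GRCh38) was the targeted gene, and among the edited lines its transcript level was lowest in the hom line and highest in the PLSF line at both days. At DIV15 it stood at 12.5 ± 0.863 CPM in WT, 8.80 ± 0.841 in the hom line and 20.2 ± 2.15 in the PLSF line (SD, n = 3). The hom line was lower than WT (log2 fold change -0.55, SE 0.13, adjusted p = 0.00235), and the PLSF line was higher (0.67, SE 0.12, adjusted p = 1.18e-04). The het line at 14.8 ± 1.01 CPM and the 4R line at 11.9 ± 0.795 CPM did not pass the test at DIV15 (adjusted p = 0.217 and 0.609). At DIV35 the WT level was 336 ± 4.82 CPM. The hom line remained lower at 227 ± 10.4 CPM (-0.56, SE 0.086, adjusted p = 2.61e-05), while the het line at 442 ± 11.3 CPM (0.39, SE 0.085, adjusted p = 9.7e-04) and the PLSF line at 550.1 ± 78.1 CPM (0.71, SE 0.085, adjusted p = 7.97e-07) were higher. The 4R line at 363 ± 49.4 CPM did not pass (adjusted p = 0.359). These are counts of the whole gene, which cannot tell 3R from 4R isoforms or edited from unedited alleles.

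**Figure D1:**
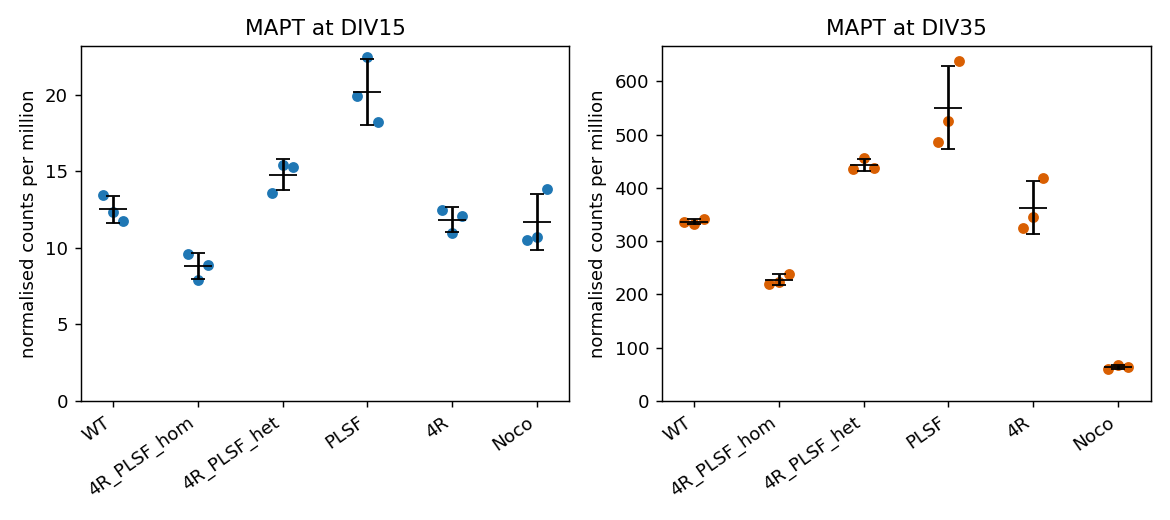
MAPT level in CPM (vertical axis, linear) in the 12 groups, with a panel for each day, each library as a point and the mean ± SD (n = 3) as a bar with whiskers. At DIV35 the groups order from Noco at 63.0 through the hom line at 227, WT at 336 and the het line at 442 to the PLSF line at 550.1.

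The comparison of WT at DIV35 with WT at DIV15 describes how unedited cultures matured. Neuronal and ventral forebrain genes rose. All 18 measured pan-neuronal genes were called higher (18 adjusted over the list alone, median 3.37, camera adjusted p = 3.03e-42), among them MYT1L (5.95, SE 0.21), NSG2 (5.78, SE 0.13) and GAP43 (4.70, SE 0.11), a growth cone protein. MAPT rose 27-fold (4.76, SE 0.11, adjusted p = 5.75e-32). Of 13 inhibitory and ventral telencephalic genes, 12 rose (12 adjusted over the list alone, median 7.77, or 7.17 with NKX2-1 at its bound, adjusted p = 7.71e-33). GAD2, which makes the transmitter GABA, went from 0.150 ± 0.187 to 103 ± 4.07 CPM (SD, n = 3). DLX1 went from 0.601 ± 0.0525 to 386 ± 1.55 and the GABA transporter gene SLC32A1 from 0.180 ± 0.0896 to 78.1 ± 4.38. NKX2-1, a regulator of the medial ganglionic eminence, had no counts at DIV15 and rose at least 153-fold. Genes that fell included LEFTY2, a NODAL antagonist with no counts at DIV35 (at least 117-fold lower), and the imprinted gene MEST (71.1 ± 5.79 to 0.191 ± 0.330 CPM, -8.43, SE 0.30).

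Among the other lists, the microtubule-associated proteins and stathmins rose in 19 of 21 (19 adjusted over the list alone, median 1.54, adjusted p = 1.34e-22), and MAP2, DCX, STMN2 and STMN4 belong to that list and to the pan-neuronal one. Glutamatergic synapse genes rose in 12 of 17 (12 adjusted over the list alone, median 2.34, adjusted p = 9.63e-09), with GRIN2B at 5.5 (SE 0.29) and the glutamate transporter gene SLC17A7 at -2.84. Deep-layer cortical genes rose in 8 of 10 (8 adjusted over the list alone, median 1.47, adjusted p = 4.9e-04), and upper-layer genes in 8 of 9 (8 adjusted over the list alone, median 1.1, adjusted p = 0.00148), where adjusted p = 0.0912 with an estimated correlation. Astrocyte and oligodendrocyte lineage genes rose in 6 of 8 (6 adjusted over the list alone, median 2.61, adjusted p = 0.00708), led by OLIG2 (5.46, SE 0.27), which ventral progenitors also express. Cholesterol synthesis genes rose in 13 of 13 (13 adjusted over the list alone, median 1.89, adjusted p = 1.99e-14). Pluripotency genes fell in 5 of 5 (5 adjusted over the list alone, median -2.14, adjusted p = 1.68e-05), with LIN28A at -4.38 (SE 0.17). Hypoxia and glycolysis genes fell in 11 of 12 (11 adjusted over the list alone, median -1.94, adjusted p = 1.78e-07), with LDHA at -3.36 (SE 0.20). Mitotic genes fell in 20 of 20 (20 adjusted over the list alone, median -0.92, adjusted p = 1.78e-07), where adjusted p = 0.220 with an estimated correlation. In all, 11373 of 17156 genes tested were called (5664 higher, 5709 lower). The antisense transcript DLX6-AS1, which cannot be separated from overlapping genes without strand, showed a ratio of 11300 (95% counting interval 3130 to 93400).

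The comparisons of the 4 edited lines with WT at DIV15 ask what the edits changed in neuronal precursors. In all 4 lines the ventral forebrain gene GSX2 and the cell adhesion genes CDH8 and CDH7 rose, and the cortical hem gene WNT8B and the collagen gene COL1A2 fell. GSX2 was at 0.270 ± 0.392 CPM in WT (SD, n = 3) and reached 20.9 ± 3.42 in the hom line, 33.9 ± 6.24 in the het line, 20.1 ± 3.18 in the PLSF line and 2.92 ± 1.89 in the 4R line. WNT8B fell from 110 ± 25.8 CPM in WT to 1.76 ± 0.945, 0.560 ± 0.157, 0.215 ± 0.139 and 7.70 ± 2.42 in the same order, with log2 fold changes of -5.97, -7.62, -8.93 and -3.86. COL1A2 changed by -4.53, -4.85, -2.88 and -3.52 from 74.4 ± 6.98 CPM, CDH8 by 3.54, 2.88, 3.14 and 4.50 from 1.86 ± 0.0558 CPM, and CDH7 by 2.87, 2.41, 2.18 and 2.14. ESRRG, an orphan nuclear receptor, rose by 2.58, 2.61, 1.73 and 1.59. The highest adjusted p among these genes and lines was 0.0105. In the 4R line the GSX2 call was lost without replicate 3 of WT at DIV15 (adjusted p = 0.0517).

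In the hom line at DIV15 further changes were in DLX1 (4.60, SE 0.36), DLX2 (2.53, SE 0.30) and the chemokine CXCL11 (4.84, SE 0.29), all higher. The ratio of WT to hom counts was 46.0 (95% counting interval 7.88 to 1850) for the transporter gene ABCG2. LDHA, the lactate dehydrogenase subunit of glycolysis, fell from 469 ± 81.3 to 60.8 ± 4.11 CPM (SD, n = 3, -2.98, SE 0.26, adjusted p = 2.38e-06). In this line 2241 genes were higher and 2348 lower than WT, 4589 in all. Without replicate 3 of WT at DIV15 there were 3707, of which 3443 were among the 4589. The lowest count with 1 library left out was 3497, without replicate 1 of the hom line, so the drop is not particular to that WT library.

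In the het line at DIV15 DLX1 rose from 0.601 ± 0.0525 to 27.0 ± 4.94 CPM (SD, n = 3, 5.43, SE 0.34), followed by DLX2 (3.07, SE 0.29) and NELL1 (2.55, SE 0.28). The lipid synthesis gene GPAT3 and the innate immune receptor gene TLR4 had no counts in this line and were at least 4.82-fold and at least 3.86-fold lower. Bounds this small mean that both genes had few counts in WT as well. The line had 4272 called genes, 2101 higher and 2171 lower, or 3529 without replicate 3 of WT, of which 3257 were shared. Leaving out replicate 3 of the het line instead gave 3371, the lowest count with 1 library left out.

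In the PLSF line at DIV15 DLX1 (5.40, SE 0.34), DLX2 (3.41, SE 0.28), the ventral and optic regulator VAX1 (3.57, SE 0.51) and the WNT receptor FZD5 (2.77, SE 0.087) rose. WNT7B fell from 177 ± 19.4 to 12.2 ± 2.29 CPM (SD, n = 3, -3.88, SE 0.22). The ratio of WT to PLSF counts was 36.0 (95% counting interval 6.08 to 1460) for the protease inhibitor gene A2M. PCDHB5, whose reads can be shared with neighbouring protocadherin copies, was at 4.05 (SE 0.13). The line had 3317 called genes, 1618 higher and 1699 lower, or 2723 without replicate 3 of WT, of which 2482 were shared. Leaving out replicate 2 of the PLSF line instead gave 2662, the lowest count with 1 library left out.

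In the 4R line at DIV15 CDH8 (43.2 ± 2.42 against 1.86 ± 0.0558 CPM, SD, n = 3), the ubiquitin ligase gene FBXO32 (2.36, SE 0.29) and PCDH17 (1.89, SE 0.13) rose. LDHA (-2.49, SE 0.25) and PDK1 (-2.05, SE 0.23), which restrains pyruvate oxidation, fell, and DLX1 did not pass the test (1.31). The line had 3323 called genes, 1654 higher and 1669 lower, or 2595 without replicate 3 of WT, of which 2351 were shared. Leaving out replicate 2 of the 4R line instead gave 2304, the lowest count with 1 library left out.

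At DIV15 cholesterol and neuronal genes were higher and hem, mesenchymal and glycolytic genes lower, with values given in the order hom, het, PLSF and 4R. Cholesterol synthesis genes rose in 13, 13, 13 and 13 of 13 members (13, 13, 13 and 13 adjusted over the list alone), with medians of 1.1, 1.17, 1.05 and 0.96 and HMGCS1, an early enzyme of the pathway, at 1.45, 1.54, 1.43 and 1.26 (camera adjusted p = 1.32e-38, 1.31e-45, 2.88e-39 and 4.57e-41). Pan-neuronal genes rose in 14, 13, 14 and 12 of 18 (14, 14, 15 and 14 adjusted over the list alone, adjusted p = 1.4e-12, 1.3e-13, 1.17e-23 and 4.89e-11), with DCX, a marker of young neurons, at 1.57, 1.62, 1.47 and 1.12. Microtubule-associated proteins and stathmins rose in 17, 13, 12 and 12 of 21 (17, 13, 13 and 15 adjusted over the list alone, adjusted p = 6.2e-12, 2.35e-09, 4.79e-13 and 9.49e-10). Inhibitory and ventral genes were called higher in 4, 4, 4 and 1 of 7 (4, 4, 4 and 3 adjusted over the list alone), and the list passed in the hom, het and PLSF lines (adjusted p = 1.05e-04, 7.45e-07 and 2.7e-08) but not in the 4R line (0.238). Cortical hem and choroid plexus genes fell in 6, 6, 7 and 5 of 9 (6, 6, 7 and 5 adjusted over the list alone, medians -1.18, -1.21, -1.85 and -0.60, adjusted p = 1.82e-05, 4.29e-09, 2.37e-12 and 0.00192), with RSPO2, a WNT agonist, at -2.05, -3.60, -3.11 and -1.36. Mesenchymal genes fell in 7, 7, 8 and 5 of 9 (7, 7, 8 and 6 adjusted over the list alone, adjusted p = 4.55e-09, 3.79e-11, 1.38e-11 and 1.13e-08), with COL6A3, a collagen gene, at 0.811 ± 0.0905 CPM in WT and 0.0622 ± 0.108, 0.0625 ± 0.0541, 0.0931 ± 0.0934 and 0.124 ± 0.0522 (SD, n = 3) in the lines. Hypoxia and glycolysis genes fell in 11, 10, 6 and 10 of 12 (11, 10, 7 and 11 adjusted over the list alone, adjusted p = 2.97e-18, 1.25e-10, 3.03e-04 and 1.94e-20). In the PLSF line adjusted p = 0.147 with an estimated correlation.

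Stress-related genes were called lower at DIV15, beside a WT library that stood apart from its mates. Replicate 3 of WT at DIV15 held 18 genes at 4 or more times the level of both other WT libraries, against 0 to 6 such genes in each of the other 35 libraries, with FOS at 48.4 CPM against 4.88 and 4.95 and HSPA6 at 52.0 against 4.52 and 9.36. Genes of p53 signalling fell in 15, 17, 16 and 12 of 18 members (16, 17, 16 and 15 adjusted over the list alone, adjusted p = 3.42e-10, 3.1e-16, 3.68e-22 and 4.16e-07), with GDF15 at -1.46, -2.32, -2.75 and -1.32. With an estimated correlation adjusted p = 0.0541 in the hom line and adjusted p = 0.110 in the 4R line, or 0.0215 and 0.111 without that WT library, where 8 members were called lower in the 4R line. Unfolded protein and integrated stress response genes fell in 12, 12, 11 and 10 of 15 (12, 12, 13 and 11 adjusted over the list alone, adjusted p = 5.47e-07, 2.35e-09, 1.97e-09 and 1.86e-05), with TRIB3, an ATF4 target, at -1.81, -2.24, -2.41 and -1.25. With an estimated correlation the 4 values were adjusted p = 0.143, 0.0747, 0.0847 and 0.233, and without that WT library they were 0.013, 0.00402, 0.00232 and 0.0983, with 11, 12, 11 and 6 members called lower. Cytosolic chaperone genes fell in 7, 6, 4 and 5 of 13 members (8, 9, 4 and 6 adjusted over the list alone, adjusted p = 8.32e-04, 7.24e-04, 0.0158 and 0.00322). With an estimated correlation adjusted p = 0.303, 0.326, 0.478 and 0.418, and without that library the calls in the PLSF and 4R lines were lost (adjusted p = 0.253 and 0.137), with 5, 4, 2 and 3 members called lower. Calls of HSPA6, FOSB, GADD45B, SNAI1 and IER3 as lower in edited lines rest on levels that this library raised in WT.

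Direct targets of WNT signalling rose at DIV15 in 5, 4, 3 and 5 of 6 members (5, 4, 3 and 5 adjusted over the list alone, adjusted p = 0.00134, 0.00354, 0.0435 and 4.22e-04), with LGR5 at 0.91, 1.07, 1.22 and 0.82. In the PLSF line the WNT list had adjusted p = 0.137 with an estimated correlation, and the call was lost without replicate 2 or 3 of WT or replicate 2 of the line (highest adjusted p = 0.0683). Intermediate progenitor and neurogenesis genes rose in 6, 6, 7 and 9 of 12 (9, 6, 7 and 9 adjusted over the list alone, adjusted p = 0.00110, 0.00266, 1.08e-06 and 1.86e-05), where adjusted p = 0.173, 0.202, 0.0545 and 0.101 with an estimated correlation. Upper-layer genes rose in 6, 6, 3 and 5 of 9 (6, 6, 3 and 6 adjusted over the list alone, adjusted p = 2.05e-04, 6.28e-04, 0.0179 and 0.00738), where adjusted p = 0.0620, 0.0744, 0.2 and 0.179 with an estimated correlation. Epithelial genes fell in 4, 4, 2 and 3 of 5 (4, 4, 4 and 3 adjusted over the list alone, adjusted p = 1.19e-05, 3.18e-06, 2.39e-04 and 2.48e-04), with KRT18 at -2.18, -2.70, -2.02 and -1.90. In the PLSF and 4R lines adjusted p = 0.0847 and 0.101 with an estimated correlation. Imprinted genes were called lower in 9, 8, 8 and 8 of 18 (9, 9, 8 and 8 adjusted over the list alone, adjusted p = 1.19e-05, 7.24e-04, 0.0119 and 8.08e-07), with H19 at -3.03, -2.99, -2.93 and -2.36.

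The comparisons of the 4 edited lines with WT at DIV35 ask what the edits changed in early neurons. In all 4 lines LHX6, NKX2-1 and SHH rose and ID1, ID3, GDF7 and RSPO2 fell. LHX6, a regulator of interneurons, went from 3.53 ± 2.00 CPM in WT (SD, n = 3) to 23.6 ± 0.525 in the hom line, 23.2 ± 4.10 in the het line, 29.8 ± 10.8 in the PLSF line and 17.4 ± 1.23 in the 4R line. NKX2-1 rose by 2.50, 1.90, 2.62 and 2.15 from 13.7 ± 5.55 CPM, the ventral morphogen gene SHH by 2.11, 2.60, 2.55 and 1.93, CDH8 by 4.37, 4.11, 3.97 and 5.47 and ARHGAP36, an activator of hedgehog signalling, by 2.16, 3.38, 3.57 and 1.64. ID1, a BMP-responsive inhibitor of differentiation, fell from 26.9 ± 8.32 CPM in WT to 1.26 ± 0.651, 0.812 ± 0.243, 0.483 ± 0.00790 and 2.07 ± 0.812, with log2 fold changes of -3.88, -5.32, -6.25 and -3.54 for ID3 and -4.36, -4.99, -5.74 and -3.66 for the roof plate BMP gene GDF7. RSPO2 was at 53.3 ± 15.0 CPM in WT and changed by -5.50, -6.20 and -3.73 in the hom, het and 4R lines. Its ratio of WT to PLSF counts was 1650 (95% counting interval 295 to 65000). The highest adjusted p among these genes and lines was 8.32e-04.

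In the hom line at DIV35 FGF10 (4.15, SE 0.49), the lipid gene ACSBG1 (2.67, SE 0.33) and LHX8 (2.16, SE 0.24), a regulator of cholinergic neurons, rose. The ratio of WT to hom counts was 29.5 (95% counting interval 7.84 to 249) for the neuropeptide Y receptor gene NPY2R and 38.7 (95% counting interval 6.57 to 1570) for the nicotinic receptor gene CHRNB4. The transcription factor gene TFAP2C went from 16.7 ± 5.84 to 0.694 ± 0.187 CPM (SD, n = 3, adjusted p = 1.63e-08). The line had 3793 called genes, 1808 higher and 1985 lower.

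In the het line at DIV35 EOMES, a marker of intermediate progenitors, fell from 21.3 ± 7.05 to 0.325 ± 0.226 CPM (SD, n = 3, -5.99, SE 0.42). For LMX1A, a roof plate regulator, the ratio of WT to het counts was 51.8 (95% counting interval 14.0 to 434). FGF10 (3.82, SE 0.51), SHH (2.60, SE 0.32) and LHX8 (2.19, SE 0.24) rose. The line had 4992 called genes, 2390 higher and 2602 lower.

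In the PLSF line at DIV35 the cortical regulator DMRTA2 fell (22.3 ± 5.29 to 0.324 ± 0.205 CPM, SD, n = 3, -6.06, SE 0.31), as did DMRT3, with a ratio of WT to PLSF counts of 92.7 (95% counting interval 25.3 to 771), and ARHGAP36 (3.57, SE 0.26) and the laminin gene LAMA3 (2.48, SE 0.30) rose. The vesicular glutamate transporter gene SLC17A6 fell by 2.10 (SE 0.28). The line had 3718 called genes, 1759 higher and 1959 lower.

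In the 4R line at DIV35 CDH8 rose from 0.666 ± 0.490 to 30.2 ± 2.26 CPM (SD, n = 3, 5.47, SE 0.23) and FGF10 by 3.41 (SE 0.53). TFAP2C (-4.55, SE 0.34), ID3 (-3.54, SE 0.35) and RSPO3 (-3.65, SE 0.41) fell. The line had 4248 called genes, 2035 higher and 2213 lower.

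The lists at DIV35, in the order hom, het, PLSF and 4R, showed lower telencephalic, hem and progenitor genes. Intermediate progenitor and neurogenesis genes fell in 11, 12, 7 and 10 of 12 members (11, 12, 9 and 10 adjusted over the list alone, medians -0.81, -0.76, -0.39 and -0.87, camera adjusted p = 8.8e-12, 2.45e-13, 3.32e-10 and 1.73e-10), with EOMES at -3.76, -5.99, -5.52 and -3.10 and NEUROG1 at -3.0, -4.30, -3.35 and -2.99. Telencephalic identity genes fell in 7, 8, 8 and 6 of 11 (7, 8, 9 and 7 adjusted over the list alone, adjusted p = 7.61e-12, 1.29e-14, 1.71e-20 and 4.29e-09), with DMRTA2 at -3.55, -4.94, -6.06 and -2.72 and EMX2 at -2.44, -2.48, -1.89 and -1.98. Radial glia genes fell in 7, 10, 9 and 7 of 17 (10, 11, 10 and 7 adjusted over the list alone, adjusted p = 9.8e-07, 5.54e-05, 6.51e-07 and 1.22e-05), with PAX6 at -1.27, -1.08, -1.77 and -0.93. Hem and choroid plexus genes fell in 7, 7, 7 and 6 of 9 (7, 7, 7 and 6 adjusted over the list alone, medians -3.03, -5.03, -5.14 and -2.30, adjusted p = 5.55e-08, 1.83e-07, 5.35e-10 and 4.56e-05), and in the 4R line adjusted p = 0.0769 with an estimated correlation. WNT targets fell in 6, 5, 5 and 4 of 6 (6, 6, 5 and 6 adjusted over the list alone, adjusted p = 5.55e-08, 3.98e-08, 5.35e-10 and 7.3e-06), with LEF1 at -2.19, -2.50, -2.42 and -1.87. Inhibitory and ventral genes rose in 8, 8, 7 and 7 of 13 (9, 8, 8 and 9 adjusted over the list alone, adjusted p = 3.86e-06, 0.00388, 0.00174 and 0.00102), with GAD1 at 1.39, 1.09, 1.15 and 1.21, although GSX2 was called lower in all 4 lines and SP8 in the hom, het and PLSF lines.

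Neuronal genes were higher and cell cycle genes lower at DIV35, in the same order of lines. Pan-neuronal genes rose in 15, 15, 11 and 15 of 18 members (16, 15, 12 and 15 adjusted over the list alone, adjusted p = 2.76e-12, 1.54e-12, 8.89e-07 and 4.06e-09), with NSG2 at 0.51, 0.82, 0.80 and 0.46. In the PLSF line adjusted p = 0.0800 with an estimated correlation. The 4R line had 0.0419, which held in 2 of 6 fits with a library left out (highest adjusted p = 0.0692). Glutamatergic synapse genes rose in 10, 12, 10 and 11 of 17 (12, 13, 10 and 11 adjusted over the list alone, adjusted p = 2.15e-05, 3.4e-08, 2.21e-04 and 1.31e-07), while SLC17A6 fell in the hom, het and PLSF lines. In the hom and PLSF lines adjusted p = 0.0963 and 0.145 with an estimated correlation. The het and 4R lines had 0.0362 and 0.0478, which held in 2 and 1 of 6 such fits (highest adjusted p = 0.0562 and 0.0772). Mitotic genes fell in 17, 18, 11 and 16 of 20 (18, 18, 17 and 16 adjusted over the list alone, medians -0.35, -0.44, -0.22 and -0.29, adjusted p = 3.72e-11, 6.53e-12, 5.65e-06 and 1.31e-07). With an estimated correlation the hom, PLSF and 4R lines had adjusted p = 0.0626, 0.174 and 0.112. The het line had 0.0466, which passed with 1 of 6 libraries left out and not with the others (highest adjusted p = 0.0777). S phase genes fell in 11, 14, 5 and 11 of 16 (14, 14, 7 and 13 adjusted over the list alone, adjusted p = 1.8e-06, 2.09e-07, 0.0116 and 5.66e-07), where adjusted p = 0.0963, 0.0752, 0.372 and 0.0769 with an estimated correlation, and the PLSF call was lost without replicate 3 of that line (adjusted p = 0.118). Cholesterol synthesis genes, higher at DIV15, fell at DIV35 in 12, 11, 4 and 13 of 13 (12, 12, 4 and 13 adjusted over the list alone, medians -0.64, -0.41, -0.19 and -0.86, adjusted p = 1.76e-14, 1.74e-05, 0.0114 and 2.75e-25). With an estimated correlation the hom, het and PLSF lines had adjusted p = 0.0563, 0.248 and 0.541, and without replicate 2 of the PLSF line its call was lost (adjusted p = 0.0641). Mitochondrially encoded genes rose in 10, 9 and 12 of 13 in the hom, het and 4R lines (12, 9 and 13 adjusted over the list alone, adjusted p = 6.77e-08, 0.00171 and 5.33e-11). With an estimated correlation the hom and het lines had adjusted p = 0.0963 and 0.304, and the 4R line had 0.0478, which passed with 1 of 6 libraries left out and not with the other 5 (highest adjusted p = 0.0779). Mitochondrial genes took 8.58% ± 0.498 of counts in the 4R line, 7.91% ± 0.075 in the hom line, 7.17% ± 0.52 in the het line and 6.36% ± 0.104 in WT at DIV35 (SD, n = 3).

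**Figure D2:**
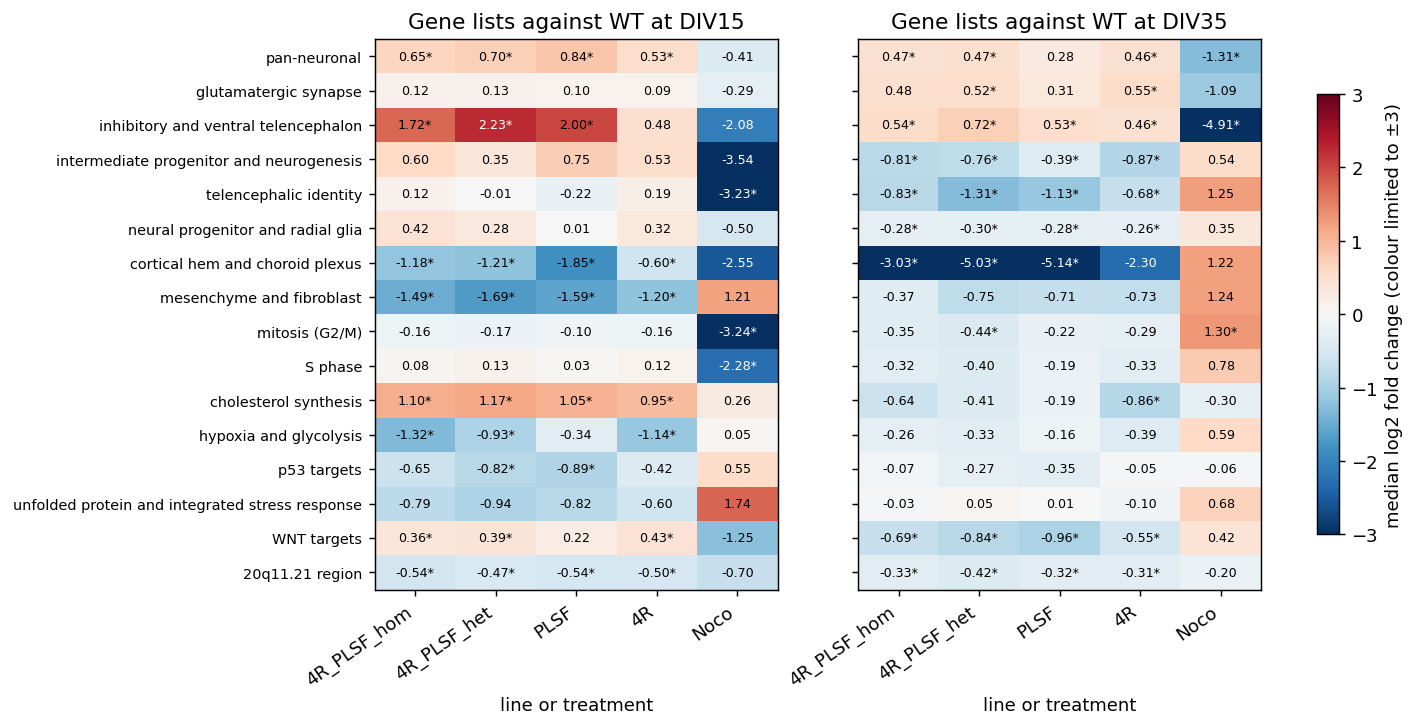
Median log2 fold change (colour, limited to ±3) of the members of a selection of the fixed gene lists (rows) in the comparisons with WT at each day (columns), where an asterisk marks a camera adjusted p under 0.05 with an estimated correlation. Cholesterol synthesis is higher in the 4 edited lines at DIV15, with medians from 0.96 to 1.17, and inhibitory and ventral genes in nocodazole cultures at DIV35 have a median of -4.91.

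Comparing the 4 lines with each other showed changes shared across genotypes. At DIV15, 829 genes were higher and 820 lower than WT in all 4 lines, and at DIV35 833 and 971, while independent lists of those sizes would share 2.97 and 3.4, and 3.77 and 5.46. Sets of 4 unchanged groups and a shared WT group were simulated 20 times per day, with each gene drawn independently. They shared at most 0 higher and 0 lower genes at DIV15 and 0 and 1 at DIV35. Both days had 139 genes higher and 161 lower in all 4 lines, among them CDH8 (higher) and NNAT and EDA2R (lower). In all 4 lines 71 genes were higher at DIV15 and lower at DIV35, and 19 lower at DIV15 and higher at DIV35. Across genes, the effects of the hom and het lines had the highest Pearson r (0.832 at DIV15 and 0.816 at DIV35) and those of the PLSF and 4R lines the lowest (0.636 and 0.641), against a simulated mean of 0.491 and 0.485 for the former pair and 0.5 and 0.492 for the latter. Covariances were 0.411 and 0.308 for hom with het, against simulated values of 0.0549 and 0.0514, and 0.266 and 0.24 for PLSF with 4R, against 0.0555 and 0.0518. At DIV35 other measures ranked the pairs differently, with a higher covariance for het with PLSF (0.318, simulated 0.0523) and a higher Spearman rho for hom with 4R (0.817 against 0.813 for hom with het). Genes are not independent replicates, and part of the excess may come from the shared WT libraries, which are too few to split. The nocodazole effect correlated with those of the 4 lines at -0.089 to 0.002 at DIV15 and -0.285 to -0.18 at DIV35, below the simulated means for unchanged groups of 0.491 to 0.5 and 0.498 to 0.508. Its covariances were -0.0973 to 0.0015 at DIV15 and -0.189 to -0.111 at DIV35, against simulated values of 0.0557 to 0.0572 and 0.0534 to 0.0542.

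The hom line was compared with the het line to ask what editing of the other allele changed. MAPT was lower in the hom line at both days (-0.76, SE 0.13, adjusted p = 0.00244 at DIV15 and -0.95, SE 0.086, adjusted p = 1.89e-07 at DIV35). PKIB, a protein kinase inhibitor gene, was higher at both days (2.42, SE 0.23 and 2.12, SE 0.20), CXCL11 was higher at DIV15 (16.3 ± 3.00 against 2.71 ± 0.239 CPM, SD, n = 3), and the malic enzyme gene ME3 was lower at DIV15 (-1.68, SE 0.18). At DIV35 the opioid receptor gene OPRK1 (1.74, SE 0.25) was higher and PCDHGB4, which shares reads with neighbouring protocadherin copies, was at -1.35 (SE 0.084). FBXO32 was higher at DIV15 (1.70, SE 0.27). The pair differed in 116 genes at DIV15 (72 higher, 44 lower in the hom line) and 110 at DIV35 (52 higher, 58 lower). Without replicates 1, 2 and 3 of the hom line in turn the counts were 40, 59 and 103 at DIV15 and 29, 58 and 49 at DIV35, and without those of the het line 48, 66 and 45, and 36, 46 and 51. Fitted with only the pair's libraries they were 298 and 305, and with DESeq2 174 at DIV35.

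The het line was compared with the 4R line to ask what P301L and S320F changed beside the 4R edit. At DIV15 DLX1 (27.0 ± 4.94 against 1.53 ± 0.329 CPM, SD, n = 3, 4.13, SE 0.29), GSX2 (3.52, SE 0.34) and DLX2 (2.58, SE 0.27) were higher in the het line, and TGFB2 (-2.86, SE 0.37) and OLFM3 (-2.68, SE 0.20) were lower. At DIV35 DMRTA2 (-2.23, SE 0.39) was lower and ARHGAP36 (1.75, SE 0.22) and AGBL4, a carboxypeptidase gene, (1.82, SE 0.22) were higher. MAPT did not pass at either day (0.31, adjusted p = 0.217 and 0.28, adjusted p = 0.0865), though at DIV35 it passed without replicate 3 of the 4R line (adjusted p = 0.00406). The pair differed in 574 genes at DIV15 (236 higher, 338 lower in the het line) and 320 at DIV35 (166 higher, 154 lower). The DIV15 count was 381 and 363 without replicates 1 and 3 of the het line and 366 without replicate 1 of the 4R line. Without replicates 1, 2 and 3 in turn the DIV35 count was 54, 65 and 949 for the 4R line and 84, 202 and 117 for the het line.

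The hom line was compared with the PLSF line to ask what the 4R edit changed beside P301L and S320F. MAPT was lower in the hom line (-1.22, SE 0.12, adjusted p = 1.8e-07 at DIV15 and -1.27, SE 0.086, adjusted p = 2.06e-10 at DIV35). COL22A1, a collagen gene, had no counts in the hom line and was at least 77.5-fold lower at DIV15 and at least 437-fold lower at DIV35. At DIV15 CXCL11 (3.88, SE 0.26) was higher and VAX1 (-3.14, SE 0.49) was lower, and at DIV35 the stress hormone gene CRH (21.6 ± 1.71 against 1.94 ± 0.731 CPM, SD, n = 3), OPRK1 (3.22, SE 0.30) and the retinoic acid hydroxylase gene CYP26B1 (3.21, SE 0.29) were higher. The pair differed in 1495 genes at DIV15 (718 higher, 777 lower in the hom line) and 1260 at DIV35 (646 higher, 614 lower). Without replicate 1 of the hom line the counts were 830 at DIV15 and 681 at DIV35, without replicates 1 and 3 of the PLSF line 906 and 875 at DIV15, and without its replicate 2 809 at DIV35.

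NNAT, EDA2R and COL22A1 were near or at 0 counts in edited lines. NNAT, an imprinted gene (chromosome 20, 37521206 to 37523693, GRCh38), held 115 to 138 counts in each of the 6 WT libraries and 0 to 3 in each of the 24 edited libraries. At DIV15 the ratio of WT to edited was 384 (95% counting interval 68.5 to 15200) in the hom line, 197 (95% counting interval 54.2 to 1630) in the het line, 199 (95% counting interval 54.8 to 1650) in the PLSF line and 197 (95% counting interval 54.2 to 1630) in the 4R line. EDA2R, a receptor of the tumour necrosis factor family (chromosome X, 66595637 to 66639298), held 100 to 204 counts in WT libraries and 0 to 3 in edited ones, and was at least 170-fold lower in the hom line at DIV15 and at least 106-fold lower at DIV35. COL22A1 (chromosome 8, 138588235 to 138914006) held 168 to 649 counts in WT and 66 to 540 in PLSF libraries, and 0 in all hom, het and 4R libraries, where it was at least 203-fold, at least 209-fold and at least 209-fold lower at DIV15 and at least 557-fold, at least 568-fold and at least 554-fold lower at DIV35. Nocodazole cultures, which were unedited, held 27 to 407 NNAT counts, 69 to 285 EDA2R counts and 158 to 334 COL22A1 counts. Outside chromosome Y, XIST and TSIX, which were left out of this search, NNAT and EDA2R were the 2 genes at 3 or fewer counts in all 24 edited libraries and at 30 or more in all 6 WT libraries. In the same search 0 genes showed the reverse. Bounds use a floor of 3 counts over the group, and intervals cover counting error only.

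**Figure D3:**
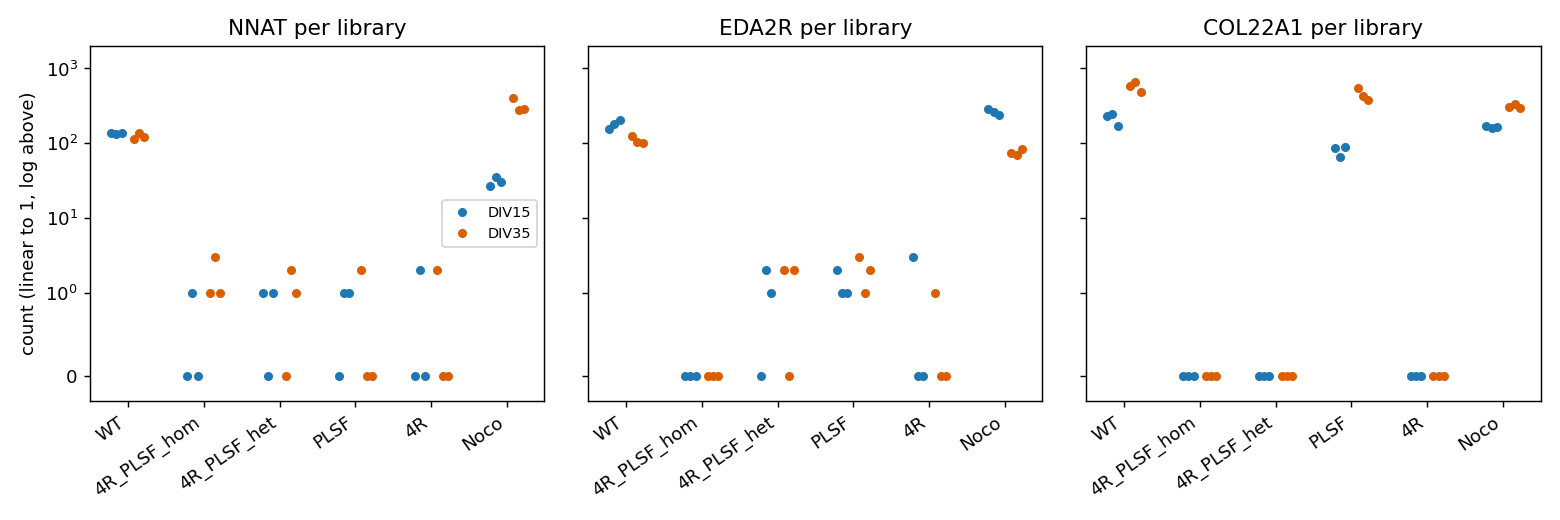
Counts (vertical axis, logarithmic above 1 and linear below) of NNAT, EDA2R and COL22A1 in each of the 36 libraries, grouped by line and day, with each library as a point. NNAT and EDA2R lie at 3 counts or fewer in the 24 edited libraries, and COL22A1 is at 0 in the hom, het and 4R lines but at 66 to 540 in the PLSF line.

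Genes at 20q11.21, a region often gained in cultured pluripotent cells, were lower in the edited lines, and medians over whole autosomes were near 0. Median log2 fold changes per autosome lay between -0.06 and 0.03 at DIV15 and between -0.07 and 0.06 at DIV35. Medians over windows of 10 Mb along the autosomes lay between -0.33 and 0.22 in the edited lines. In the 4R line the window at 30000001 to 40000000 of chromosome 20 was at -0.032 at DIV15 and -0.083 at DIV35. A median over a whole autosome or such a window cannot show a change confined to a few neighbouring genes. In the 20q11.21 list, 9, 9, 9 and 8 of 13 members were called lower at DIV15 (10, 10, 9 and 8 adjusted over the list alone, camera adjusted p = 3.04e-05, 1.19e-05, 7.65e-07 and 1.2e-05). The numbers were 8, 7, 8 and 7 at DIV35 (9, 7, 9 and 8 adjusted over the list alone, adjusted p = 1.98e-08, 2.07e-06, 1.57e-07 and 2.25e-07). Without replicate 3 of WT the list medians at DIV15 were -0.599, -0.448, -0.53 and -0.546 in the hom, het, PLSF and 4R lines. Whether the copy number of the region differs between WT and the lines was not tested. At DIV15 ID1 was at -2.42, -2.83, -2.89 and -1.99, POFUT1, a fucosyltransferase acting on NOTCH, at -0.75, -0.72, -0.86 and -0.67, and the anti-apoptotic gene BCL2L1 was at -0.29, -0.36, -0.42 and -0.31.

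Nocodazole served as a control treatment of WT cultures. The sample labels give 3 uM for 72 h and the treatment protocol 3 nM for 36 h before collection, so dose and duration are uncertain. At DIV15 forebrain and cell cycle genes were lower in treated precursors, and autophagy genes and the YAP target ANKRD1 were higher. LMO3 fell from 51.7 ± 14.6 to 0.278 ± 0.304 CPM (SD, n = 3, -7.47, SE 0.39, adjusted p = 6.94e-11). The proneural gene NEUROG1 had no counts after treatment (at least 83.7-fold lower). ANKRD1 rose from 0.510 ± 0.495 to 703 ± 19.1 CPM. The cytokine gene IL11 rose from 1.26 ± 1.33 to 650.3 ± 59.0, TFPI2 from 1.17 ± 0.242 to 895 ± 47.5 and ETS1 from 0.330 ± 0.0512 to 334 ± 15.0. MAPT stood at 11.7 ± 1.85 CPM against 12.5 ± 0.863 and did not pass (adjusted p = 0.613). Mitotic genes fell in 20 of 20 (20 adjusted over the list alone, median -3.24, adjusted p = 2.6e-36), with TOP2A at -4.03, and S phase genes in 16 of 16 (16 adjusted over the list alone, median -2.28, adjusted p = 3.96e-21). Telencephalic identity genes fell in 11 of 11 (11 adjusted over the list alone, median -3.23, adjusted p = 9.27e-12) and deep-layer genes in 7 of 7 (7 adjusted over the list alone, median -3.13, adjusted p = 8.17e-04). Neurogenesis genes fell in 11 of 12 (11 adjusted over the list alone, median -3.54, adjusted p = 5.28e-07), where adjusted p = 0.0750 with an estimated correlation. Autophagy and lysosome genes rose in 14 of 15 (14 adjusted over the list alone, median 1.01, adjusted p = 5.25e-06), with MAP1LC3B at 2.67 (SE 0.084). Unfolded protein and integrated stress response genes rose in 12 of 15 (12 adjusted over the list alone, median 1.74, adjusted p = 0.00508), where adjusted p = 0.407 with an estimated correlation, or 0.00861 without replicate 3 of WT. Epithelial genes rose in 4 of 5 (4 adjusted over the list alone, median 1.81, adjusted p = 1.48e-04) and mesenchymal genes in 5 of 9 (5 adjusted over the list alone, median 1.21, adjusted p = 0.00761), where adjusted p = 0.0813 and 0.138 with an estimated correlation, or 0.0365 and 0.126 without replicate 3 of WT. Pluripotency genes fell in 5 of 5 (5 adjusted over the list alone, median -2.01, adjusted p = 0.00508) and WNT targets in 4 of 6 (4 adjusted over the list alone, median -1.25, adjusted p = 0.0149), the latter with adjusted p = 0.0978 with an estimated correlation. Tubulin genes went both ways, with TUBB6 at 3.59 and TUBB4A at -3.05. Of 16193 genes tested, 11440 were called (5624 higher, 5816 lower), and without replicate 3 of WT 11309.

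At DIV35 ventral forebrain and neuronal genes were lower in treated cultures, while mitotic genes were higher than in WT. NKX2-1 fell from 13.7 ± 5.55 to 0.124 ± 0.0551 CPM (SD, n = 3, -6.66, SE 0.89), SLITRK6 from 34.9 ± 1.39 to 0.341 ± 0.111 and MAPT from 336 ± 4.82 to 63.0 ± 3.97 (-2.41, SE 0.093, adjusted p = 6.57e-17). The ratio of WT to treated counts was 129 (95% counting interval 22.7 to 5120) for LHX8 and 178 (95% counting interval 48.9 to 1480) for the glutamate receptor gene GRM4. THBS1, an extracellular matrix protein, rose from 2.38 ± 0.333 to 88.7 ± 14.5 CPM, TNFRSF12A by 5.27 (SE 0.23) and EBF2, a marker of Cajal-Retzius neurons, by 4.74 (SE 0.30). Inhibitory and ventral genes fell in 13 of 13 (13 adjusted over the list alone, median -4.91, adjusted p = 3.31e-59), with DLX1 at -5.80 and SLC32A1 at -5.43. Pan-neuronal genes fell in 17 of 18 (17 adjusted over the list alone, median -1.31, adjusted p = 6.78e-18), with MYT1L at -2.61 and DCX at -2.11. Mitotic genes rose in 19 of 20 (19 adjusted over the list alone, median 1.30, adjusted p = 2.89e-28), with CCNB1 at 2.16, and S phase genes in 16 of 16 (16 adjusted over the list alone, median 0.78, adjusted p = 1.56e-08), where adjusted p = 0.0977 with an estimated correlation. Glutamatergic synapse genes fell in 12 of 17 (12 adjusted over the list alone, median -1.09, adjusted p = 1.13e-05), microtubule-associated proteins and stathmins in 15 of 21 (15 adjusted over the list alone, median -0.64, adjusted p = 4.72e-07) and tubulins in 6 of 11 (6 adjusted over the list alone, median -0.91, adjusted p = 0.0144), where adjusted p = 0.0999, 0.0977 and 0.332 with an estimated correlation. Telencephalic identity genes rose in 8 of 11 (8 adjusted over the list alone, median 1.25, adjusted p = 0.0144), where adjusted p = 0.145 with an estimated correlation, with EMX1 at 4.92, although SIX3 (-4.43) fell. Unfolded protein and integrated stress response genes rose in 11 of 15 (11 adjusted over the list alone, median 0.68, adjusted p = 9.5e-05) and hypoxia and glycolysis genes in 8 of 10 (8 adjusted over the list alone, median 0.60, adjusted p = 5.48e-05), where adjusted p = 0.0977 and 0.0555 with an estimated correlation. Of 16008 genes tested, 9928 were called (4887 higher, 5041 lower).

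The difference of each effect between the days was tested directly. GSX2 was higher than in WT at DIV15 and lower at DIV35, with differences between the effects in the hom (-7.21, SE 0.43), het (-7.68, SE 0.41) and PLSF (-6.53, SE 0.44) lines. TFAP2C moved in the same direction in the hom (-5.29, SE 0.38) and 4R (-5.52, SE 0.37) lines. The effect was more positive at DIV35 for the retinoic acid receptor gene RARB in the PLSF line (4.37, SE 0.34) and for BCL11B, a regulator of deep-layer neurons, in the 4R line (4.51, SE 0.89). EOMES (-6.58, SE 0.39) and DLX1 (-5.62, SE 0.32) had a lower effect at DIV35 in the het line. The effect on MAPT did not pass the test of a difference between the days in the edited lines (adjusted p = 0.949, 0.470, 0.927 and 0.385 in the hom, het, PLSF and 4R lines), and it differed for nocodazole (-2.37, SE 0.16, adjusted p = 2.32e-16). Of 17156 genes tested, the hom line had 2839 (1078 with a higher effect at DIV35, 1761 with a lower one), the het line 3500 (1366 and 2134), the PLSF line 2674 (1006 and 1668), the 4R line 2572 (989 and 1583) and nocodazole 10850 (5175 and 5675). Without replicate 3 of WT at DIV15 the counts were 2240, 2951, 2143, 2092 and 10650.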

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

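The splits of libraries at DIV15 and for nocodazole between days, all tests of NNAT, EDA2R and COL22A1, the tests of shared WT noise and of a WT culture difference, and all tests of the nocodazole pattern were chosen only after the result was seen.

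The effects of the lines and of nocodazole differed between DIV15 and DIV35 by a direct test of the difference in 2839 genes in the hom line, 3500 in the het line, 2674 in the PLSF line, 2572 in the 4R line and 10850 for nocodazole. In the hom line the log2 effect went from 6.18 to -1.03 for GSX2 (difference -7.21, adjusted p = 1.58e-12), from 0.72 to -4.56 for TFAP2C (-5.29, adjusted p = 2.18e-12), from 0.82 to -4.45 for FAP (-5.28, adjusted p = 4.37e-08) and from 1.52 to -3.27 for BHLHE22 (-4.79, adjusted p = 1.17e-05). In the het line it went from 6.88 to -0.80 for GSX2 (-7.68, adjusted p = 1.51e-13), from 0.58 to -5.99 for EOMES (-6.58, adjusted p = 9.34e-14) and from 5.43 to -0.18 for DLX1 (-5.62, adjusted p = 1.39e-13). In the PLSF line it went from 6.14 to -0.38 for GSX2 (-6.53, adjusted p = 1.4e-11) and from -2.25 to 2.13 for RARB (4.37, adjusted p = 2.68e-12). In the 4R line it went from 0.97 to -4.55 for TFAP2C (-5.52, adjusted p = 8.58e-13), from 0.89 to -4.44 for FAP (-5.33, adjusted p = 5.68e-08), from 1.13 to -3.33 for NEUROG2 (-4.46, adjusted p = 6.67e-08) and from -3.14 to 0.85 for C22orf42 (3.99, adjusted p = 4.26e-07). For nocodazole the fitted differences were 11.79 for NEUROG1 (adjusted p = 4.79e-18), 10.17 for GJD2 (adjusted p = 6.31e-14), 9.07 for EBF2 (adjusted p = 4.22e-19), 8.93 for EOMES (adjusted p = 1.72e-20), 8.92 for NEUROG2 (adjusted p = 7.57e-13), -8.68 for RGS6 (adjusted p = 1.92e-25), -9.45 for CPA4 (adjusted p = 3.11e-19) and -2.37 for MAPT (adjusted p = 2.32e-16). Where a group had no counts, as NEUROG1 after nocodazole at DIV15, the fitted difference depends on the prior count and is no bound.

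Other splits of the same libraries were tested with the same fit. For the differences between days, 1 of 25 drawn splits, the real one, gave as many genes. This share of 0.04 is the smallest that 25 splits can give and was not adjusted over the 5 results. These splits exchanged libraries of WT and the line within each day, so they also broke any line effect that was equal at both days. They therefore cannot decide whether chance accounts for a difference between the days. The highest other split gave 1651 genes for the hom line, 2421 for the het line, 1051 for the PLSF line, 2166 for the 4R line and 8524 for nocodazole. Splits of 3 against 3 libraries number 10, too few for a share under 0.05, and the real split, 1 of the 10, gave more genes than any other. Every other split mixed libraries of both groups, so any difference between them widened the spread within groups and lowered the calls. Few calls there were due in advance and cannot decide whether chance accounts for the real counts. Against 11373 genes in the WT comparison between days the highest other split gave 0. At DIV15 it gave 0, 0, 0, 1 and 0 genes against 4589, 4272, 3317, 3323 and 11440 for the hom, het, PLSF and 4R lines and nocodazole, and 0, 1 and 0 against 116, 574 and 1495 for hom with het, het with 4R and hom with PLSF. At DIV35 it gave 2, 0, 1, 0 and 1 against 3793, 4992, 3718, 4248 and 9928 for the same comparisons with WT, and 0, 2 and 53 against 110, 320 and 1260 between lines.

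NNAT and EDA2R were at 3 or fewer counts in all 24 edited libraries, and COL22A1 at 0 in the hom, het and 4R lines. Loss of a segment holding most of the 20 nearest tested genes is argued against, since their lowest median log2 fold change was -0.081 around NNAT, -0.039 around EDA2R and -0.027 around COL22A1, and so is library depth, since at the WT share at least 122.4 NNAT counts would be due in each edited library. Loss of a smaller segment stays open, since the highest log2 fold change of the nearest tested gene, 0.608 at NNAT, 0.031 at EDA2R and 0.131 at COL22A1, only limits its reach. HEPH, the tested gene nearest to EDA2R at DIV15, was at a fitted log2 fold change of -2.57 or lower in the 4 lines (highest adjusted p = 2.27e-05) and at 0.996 after nocodazole, and it was singled out after its values were seen. It was not tested at DIV35. P301L and S320F cannot be the whole cause for NNAT and EDA2R, since both were at a fitted log2 fold change of -7.25 or lower in the 4R line, which lacks them, and the 4R edit cannot be, since both were at -5.69 or lower in the PLSF line, which lacks it. For COL22A1, which in the PLSF line was at -1.41 at the lowest, an effect of the 4R edit and a founder clone shared by the other 3 lines cannot be told apart, as each genotype is 1 line. An edit-independent change fixed in the edited clones, an effect of any MAPT edit, or a difference of the WT cultures unrelated to the edits may account for NNAT and EDA2R. All of these stay open, and none was tested.

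The same genes were called in the same direction in all 4 edited lines, 1649 at DIV15 and 1804 at DIV35. A single WT library is argued against, since at least 1249 at DIV15 and 1301 at DIV35 were called with any 1 WT library left out, and 1144 and 1262 of these were among the genes called with all 3. Noise of the shared WT libraries that is independent between genes is argued against, since simulated unchanged groups shared at most 0 genes at DIV15 and 1 at DIV35. The simulation held no variation shared between genes, so it cannot judge noise of that kind in the WT libraries. A trend with GC content and gene length is argued against, since it explained 0.025 and 0.014 of the variance. A difference of the WT cultures unrelated to the edits cannot be told apart from an effect of any MAPT edit, since both need the 4 lines to move together, and the lowest r between a pair of lines was 0.636. An effect common to the edits is a hypothesis that more WT and unedited clones could test.

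Mitotic genes were lower after nocodazole at DIV15 (median -3.24) and higher at DIV35 (1.30). An exchange of WT and nocodazole libraries at DIV35 is argued against, since the WT libraries correlated with the mean of the edited lines at 0.984 or higher and the nocodazole libraries at 0.907 or lower. A loss of neurons that lowers 5 neuronal lists by a like amount at DIV35 is argued against, since their median log2 fold changes spanned 4.73. The lists need not fall alike when neurons are lost. A loss of neurons with a relative gain of dividing cells therefore stays open and was not tested. Library depth cannot be judged from the mean totals, which differed by 1.03 times but may have been equalised before deposit. A biological difference between precursors and neurons in their response stays open, as does a difference in the dose or time given at the 2 days, which the labels leave uncertain, and neither was tested.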

How the results depend on the processing

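The gene lists with each library left out were chosen after seeing the data, and all other settings before. Of 22 gene counts, all were within 1.5 times the reported value with median-of-ratios factors, without a filter on low counts and with a replicate block, 21 with DESeq2 and 20 with only the groups compared. The exceptions were hom with het, with 298 genes at DIV15 and 305 at DIV35 with only the groups compared and 174 at DIV35 with DESeq2, and the cause was not tested. With 1 library left out, 137 counts were within that range and 25 were not, all of them between edited lines. Hom with het spanned 40 to 103 genes at DIV15 and 29 to 58 at DIV35, het with 4R 363 to 482 and 54 to 949, and hom with PLSF 830 to 1227 and 681 to 1496, where fewer samples lower the number of calls but the rises to 949 without replicate 3 of the 4R line and to 1496 without replicate 2 of the hom line have no tested cause. Of 193 list calls, 98 held with an estimated correlation, 189 with fry and 193 with a replicate block, and with a library left out 1129 held and 29 were lost at the preset correlation. Of the 98 calls, 14 were lost at the estimated correlation without at least 1 library, in 45 of 588 tests. Of the named values 406 kept their side of the threshold with DESeq2 (7 lost the call, 1 gained it), 413 with median-of-ratios factors (1 lost it) and 410 with a replicate block (3 lost it, 1 gained it). With a library left out 2664 did, 149 lost the call and 1 gained it, and no named value changed direction under these settings. MAPT in het with 4R at DIV35 passed with DESeq2 (adjusted p = 0.049956), with a replicate block (0.0301) and without replicate 3 of the 4R line (0.00406), and was at 0.0865 in the reported fit. Of 20 similarities 19 kept their sign among called genes. That of the 4R line and nocodazole at DIV15 went from 0.002 to -0.025, the cause was not tested, and both values are near 0. At this depth the smallest folds tested on simulated data, 1.5-fold, were recovered in 52.2% to 68.7% of genes.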

Other observations

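The list calls with a library left out were tested only after the data had been seen. Genes near MAPT at 17q21 were called higher in 2, 2, 1 and 3 of 11 members at DIV15 (2, 1, 1 and 4 adjusted over the list alone, adjusted p = 0.476, 0.296, 0.382 and 0.209) and 1, 4, 2 and 3 of 12 at DIV35 (1, 4, 2 and 3 adjusted over the list alone, adjusted p = 0.537, 0.247, 0.271 and 0.351) in the hom, het, PLSF and 4R lines, and the list did not pass in any of them. Microtubule-associated proteins and stathmins at DIV35 were called higher in 15, 17, 13 and 15 of 21 (18, 19, 15 and 15 adjusted over the list alone, adjusted p = 4.16e-07, 1.77e-08, 1.45e-06 and 7.92e-07), where adjusted p = 0.0626, 0.0362, 0.0800 and 0.0693 with an estimated correlation. Tubulins fell at DIV35 in 6 of 11 in the hom line (6 adjusted over the list alone, adjusted p = 0.0233) and 7 in the 4R line (7 adjusted over the list alone, adjusted p = 0.00207), where adjusted p = 0.462 and 0.305 with an estimated correlation, and the hom call was lost without replicate 3 of WT or replicate 1 of the line (highest adjusted p = 0.137). Cajal-Retzius genes fell in the PLSF line at DIV35 in 4 of 8 (4 adjusted over the list alone, adjusted p = 0.00115), where adjusted p = 0.0618 with an estimated correlation, and neural crest genes in 4 of 5 (4 adjusted over the list alone, adjusted p = 4.97e-04), where adjusted p = 0.0434 with an estimated correlation and 2 of 6 libraries left out in turn ended that call (highest adjusted p = 0.0622). Deep-layer genes at DIV15 were called higher in 4 of 7 in the het line (4 adjusted over the list alone, adjusted p = 0.0245, and adjusted p = 0.0661 with an estimated correlation) and 3 in the PLSF line (3 adjusted over the list alone, adjusted p = 0.0119). Midbrain and diencephalic genes were called higher in 4 of 7 in the 4R line at DIV15 (5 adjusted over the list alone, adjusted p = 0.0326), where adjusted p = 0.110 with an estimated correlation, and the call was lost without replicate 2 of WT or of the line (highest adjusted p = 0.0657).

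Interferon response genes were called lower at DIV15 in 3, 4, 3 and 3 of 8 members (3, 4, 4 and 4 adjusted over the list alone, adjusted p = 0.0353, 0.00384, 0.00860 and 0.0133), where adjusted p = 0.132, 0.0385, 0.0545 and 0.0984 with an estimated correlation, and the hom call was lost without replicate 3 of WT or of the line (highest adjusted p = 0.0597). Autophagy and lysosome genes were called lower at DIV15 in 8 of 15 in the het line (8 adjusted over the list alone, adjusted p = 0.0123) and 6 in the PLSF line (8 adjusted over the list alone, adjusted p = 0.0172), where adjusted p = 0.155 and 0.169 with an estimated correlation, and both calls were lost without replicate 3 of WT (adjusted p = 0.0523 and 0.06). After nocodazole, immediate early genes were called higher in 6 of 12 at DIV15 (5 adjusted over the list alone, adjusted p = 0.0114) and 6 of 11 at DIV35 (6 adjusted over the list alone, adjusted p = 0.0424), where adjusted p = 0.407 and 0.0999 with an estimated correlation. NRF2 targets were called higher in 7 of 10 at DIV15 (7 adjusted over the list alone, adjusted p = 0.0354) and 9 at DIV35 (9 adjusted over the list alone, adjusted p = 0.0225), where adjusted p = 0.333 and 0.133 with an estimated correlation, and 0.0365 at DIV15 without replicate 3 of WT. Astrocyte and oligodendrocyte lineage genes fell at DIV35 in 5 of 7 (5 adjusted over the list alone, adjusted p = 0.0240), where adjusted p = 0.0999 with an estimated correlation, and the call was lost without replicate 1 of nocodazole (adjusted p = 0.0702). All 3 tested endoderm genes were called higher after nocodazole at DIV15 (3 adjusted over the list alone), and the list did not pass (adjusted p = 0.262). Without replicate 3 of WT at DIV15 other list calls also crossed the threshold with an estimated correlation, upper-layer genes in the hom line (adjusted p = 0.0496) and deep-layer genes in the het line (0.0319) by passing, and interferon response (0.0547) and WNT targets (0.0522) in the het line, imprinted genes in the PLSF line (0.0597) and microtubule-associated proteins and stathmins in the 4R line (0.0573) by no longer passing. Members called fell from 5 to 3 for WNT targets in the hom line, from 8 to 4 and 6 to 4 for autophagy and lysosome genes in the het and PLSF lines, and from 3 to 2 for interferon response in the PLSF and 4R lines, upper-layer genes in the PLSF line and epithelial genes in the 4R line. At the estimated correlation the calls lost most often with each of 6 libraries left out in turn were those in the 4R line at DIV35 of pan-neuronal (adjusted p = 0.0419, highest 0.0692, kept in 2), glutamatergic synapse (0.0478, highest 0.0772, kept in 1) and mitochondrially encoded genes (0.0478, highest 0.0779, kept in 1), and in the het line at DIV35 of mitotic (0.0466, highest 0.0777, kept in 1) and glutamatergic synapse genes (0.0362, highest 0.0562, kept in 2) and of microtubule-associated proteins and stathmins (0.0362, highest 0.0699, kept in 2). Kept in 3 of 6 at DIV15 were microtubule-associated proteins and stathmins in the 4R line (0.0345, highest 0.0573) and WNT targets (0.0375, highest 0.0527) and interferon response (0.0385, highest 0.0694) in the het line. Kept in 4 or 5 of 6 at DIV15 were epithelial genes in the hom line (0.0443, highest 0.0737), deep-layer (0.0468, highest 0.0591) and imprinted genes (0.0407, highest 0.0658) in the PLSF line and hem and choroid plexus genes in the 4R line (0.0303, highest 0.0538). At DIV35 neural crest genes in the PLSF line were kept in 4 of 6 (0.0434, highest 0.0622). Over 256 windows of the autosomes with at least 20 tested genes, window medians in the edited lines lay between -0.33 and 0.22. Chromosome X was not included.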
